A study of Mus musculus with 6 samples.

How the data were processed

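Total RNA of the cortex of 6 mouse embryos at E12.5 was profiled, 3 control and 3 Lats1/Lats2 DKO, and the labels state that each sample came from an independent embryo. Per the labels, RNA was extracted with Trizol, sense-strand cDNA was made from 100 ng of RNA with a whole-transcript kit, and the fragmented cDNA was labelled with biotin. The deposited values are on a log2 scale and were made by RMA (robust multi-array average) per the submitters' processing notes. The version of RMA and the software that ran it were not given in the sources used here. RMA corrects background, makes the distributions of all arrays equal by quantile normalization and summarises the probes of a row. The log2 values of the authors therefore carry no information on a change of the total amount of RNA per cell, and an increase or decrease common to all transcripts would not be seen. Scanner files were not used here, so the normalization could not be repeated from the probes, and no detection call was at hand to tell a dim row from background.

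The table held 41345 rows. Gene symbols came from a table of the platform's annotation, which listed 25335 of the rows. Of these, 23521 had 1 gene symbol and 1814 had several, and the remaining 16010 rows are unnamed here. The symbols of 23328 one-symbol rows were compared through their gene identifiers with the RefSeq gene table of assembly GRCm38.p6, and all 23328 had the same symbol there. Rows with several symbols or none were left out of the comparison. The one-symbol rows covered 22180 genes, and for each of the 1082 genes with more than 1 row the row with the highest mean over all 6 arrays was used. Among the changed genes 20 had more than 1 row, and the rows of 1 of them differed in sign. Genes whose mean over the 6 arrays lay below the 25th percentile of the one-symbol rows, a log2 value of 5.02, were left out, which removed 5456 genes and left 16724. No genome coordinates are given, since the build of the probes was not given in the sources used here.

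DKO was compared with control by linear models (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided), with no covariate and no further normalization. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The 6 arrays gave 4 residual degrees of freedom, to which the empirical Bayes step added 4.44, and the median residual SD was 0.0951. Fold changes are DKO minus control on the log2 scale. The genes named in the text were chosen by a rule: Lats1 and Lats2, the 12 largest increases and 12 largest decreases among changed genes whose groups did not overlap, and for each gene list the 4 members with the smallest p. Unnamed clones and families with shared probes were passed over in the 12 and 12. Genes named outside this rule are said to have been chosen after their values were seen.

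Gene lists were fixed for YAP/TAZ targets, Hippo components, p53 targets, DNA damage response, DNA replication, mitosis, ribosome biogenesis, RNA polymerase II machinery, apical progenitors, intermediate progenitors and neurogenic genes, neurons, ventral telencephalon, hem and choroid plexus, meninges, endothelium, erythroid cells, microglia, surface epithelium, retina, actin and focal adhesions, hypoxia and glycolysis, stress responses and immediate early genes. A list of sex-linked genes served as a check of the embryos only. Together the lists named 441 members, of which 413 had a row and 28 did not. The lists, the tests, the filter, the naming rule and the other settings tried were set before the data were examined. Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes and adjusted over 23 lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. With its preset correlation camera calls lists readily when the genes of a list vary together between embryos. Fry's directional p tests whether the genes of a list move on balance one way and does not compare them with other genes.

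The scripts were tested on simulated data drawn for the DKO against control comparison over 16724 genes, with 200 changed genes in each of 5 draws. They recovered 71.6% of genes changed by 0.5 on the log2 scale, 97% at 1 and 100% at 1.5, with 6.07% false calls among the calls. A list shifted by 0.3 was found in 5 of 5 draws, and 0 other lists were called. The simulated genes varied independently of each other. These draws therefore cannot show how often camera calls a list wrongly when its genes vary together.

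Arrays were compared before use. The Pearson correlations between arrays over all rows lay between 0.978 and 0.994, and no pair held the same values, so each array counted as 1 sample. Control and DKO samples carry the same replicate numbers, which the labels do not tie to litters or days, and a fit with the number as a block was an alternative. Other settings set in advance were no filter and a stricter filter on dim genes, a repeated quantile normalization, each array's median set to 0, trended and robust variance estimates, array weights, all rows or the mean of a gene's rows, unmoderated statistics, stricter thresholds and leaving out each array in turn. After seeing the data, a covariate for the Y-linked genes and a fit without genes on chromosomes X and Y were added. Comparisons of single genes outside limma used exact permutation tests over the 6 arrays. Data handling and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.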

Results

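Gene expression was measured in the dissected cortex of 6 mouse embryos at stage E12.5, each sample coming from a separate embryo according to the labels. There were 3 control embryos and 3 embryos with loxP-flanked Lats1 and Lats2 alleles and a Nestin-Cre transgene, called DKO (double knock-out) here. Nestin-Cre drives recombination in neural progenitors and their descendants. Lats1 and Lats2 are the kinases of the Hippo pathway that phosphorylate and restrain the transcriptional coactivators YAP and TAZ. Each sample was hybridised to 1 Affymetrix whole-transcript array, and the deposited values were on a log2 scale. The array medians lay between 5.94 and 5.97, and the number of arrays per group (3) limited the precision of every value. The comparison asked which transcripts differed in level between DKO and control cortex.

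The targeted genes were examined first. Lats1 was lower in the DKO cortex, at 7.79 ± 0.05 (SD, n = 3) against 8.71 ± 0.33 (SD, n = 3) in control cortex, a log2 fold change of -0.91 ± 0.14 (SE) with a limma adjusted p of 0.0189. This was a 1.88-fold lower signal, and all 3 DKO arrays lay below all 3 control arrays. Lats2 was not lower: its mean was 7.27 ± 0.09 (SD, n = 3) in DKO and 7.03 ± 0.17 (SD, n = 3) in control cortex, a log2 fold change of 0.24 ± 0.10 (SE) with a limma adjusted p of 0.285. An exact two-sided permutation test gave p = 0.1 for each of the 2 genes, the smallest p that 3 arrays against 3 allow. Neither the deleted exons nor the positions of the probes were given in the sources used here, so a Lats2 probe set outside the deleted part would check nothing. The Lats1 call was lost in 4 of the 6 fits that left out 1 array, each with fewer samples than the main fit. The limma adjusted p of Lats1 was 0.0809 without control 1, 0.0571 without control 3, 0.0875 without DKO 1 and 0.0811 without DKO 3. Its log2 fold changes in these fits were -0.86, -0.78, -0.93 and -0.89.

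Expression in the DKO cortex differed from control mainly by increases. Of 16724 genes tested, 228 rose and 60 fell, so that 79.2% of the 288 changed genes were higher in DKO. These counts changed when 1 array was left out, which also left fewer samples in the fit. In these fits 137 rose and 11 fell without control 1, 140 and 53 without control 2, and 121 and 13 without control 3. The counts were 131 and 14 without DKO 1, 260 and 54 without DKO 2, and 130 and 14 without DKO 3. With a trended variance 323 rose and 162 fell. Among these 16724 genes Thbs1, which encodes the secreted matrix glycoprotein thrombospondin 1, rose most, by 3.24 ± 0.09 (SE) on the log2 scale or 9.44-fold. It was followed by Lrp2, an endocytic receptor also known as megalin, at 5.02-fold, and by Steap1, a protein of the cell membrane, at 2.32 ± 0.15 (SE) on the log2 scale. The largest decrease among genes past the threshold was that of Rlbp1, which encodes a retinaldehyde-binding protein, by a log2 change of -1.11 ± 0.19 (SE). Increases were also larger than decreases: 140 genes rose and 12 fell by 1.5-fold or more, and 51 rose and 1 fell by 2-fold or more.

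**Figure D1:**
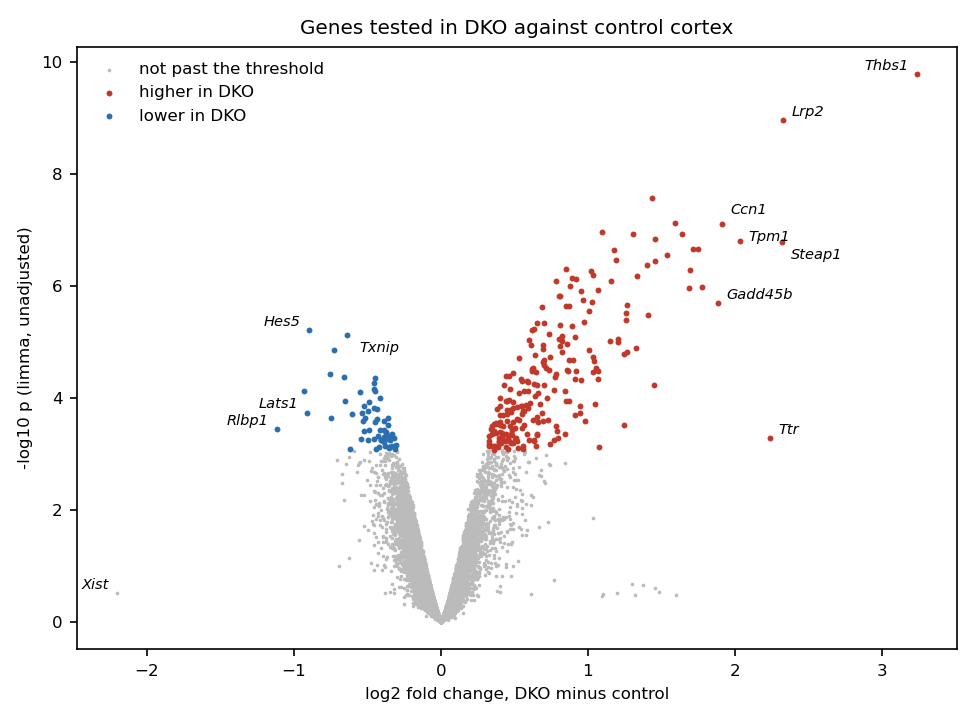
Each point is 1 of the 16724 tested genes, with the log2 fold change (DKO minus control, 3 arrays each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 228 genes higher in DKO are red, the 60 lower are blue, and the remaining genes are grey, with Xist among the genes that did not pass.

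The 12 largest increases among genes past the threshold were those of Thbs1, Lrp2, Steap1, Ttr, Tpm1, Ccn1, Gadd45b, Col12a1, Cldn12, Ccn2, Large2 and Cntn6, with log2 fold changes from 3.24 down to 1.69. Thbs1 went from 7.50 ± 0.13 (SD, n = 3) in control to 10.74 ± 0.12 (SD, n = 3) in DKO cortex, and Lrp2 from 5.59 ± 0.13 (SD, n = 3) to 7.92 ± 0.08 (SD, n = 3). Tpm1, which encodes an actin-binding tropomyosin, rose by 2.04 ± 0.13 (SE), and Col12a1, which encodes a collagen chain, by 1.78 ± 0.14 (SE). Cldn12, a claudin, rose by 1.75 ± 0.12 (SE). Cntn6, a neural cell adhesion molecule, rose to 6.52 ± 0.20 (SD, n = 3) in DKO from a control mean of 4.83, which lies under the limit for dim genes (5.02) and was not shown to be above background, so the size and rank of its increase are uncertain. Ttr, the thyroid hormone carrier made in quantity by the choroid plexus, had the widest error in this set, at 2.24 ± 0.41 (SE), because DKO 2 stood at 10.25 and the other DKO arrays at 8.84 and 8.33. Of these 12 genes, 11 stayed past the threshold in each of the 6 fits that left out 1 array. The exception was Ttr, with adjusted p = 0.132 without control 1, 0.0749 without control 2, 0.141 without control 3 and 0.106 without DKO 1.

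The 12 largest decreases were those of Rlbp1, Ndrg2, Lats1, Hes5, Aldoc, Kcnh7, Ptpru, Txnip, Ppp2r2b, Slc16a14, Ube2ql1 and Gadd45g, with log2 fold changes from -1.11 to -0.53. Hes5, a transcriptional repressor induced by Notch signalling, fell by 0.90 ± 0.09 (SE) on the log2 scale, from 10.09 ± 0.08 (SD, n = 3) to 9.20 ± 0.16 (SD, n = 3). Aldoc, the aldolase isoform of brain, fell by 0.76 ± 0.10 (SE), and Txnip, the thioredoxin-interacting protein, fell by 0.64 ± 0.07 (SE). Ptpru, a receptor tyrosine phosphatase, fell by 0.66 ± 0.09 (SE). Hes5, Aldoc, Ptpru and Txnip stayed past the threshold in each fit that left out 1 array, and the other 8 did not. For Rlbp1 the adjusted p reached 0.103 without control 1, for Ndrg2 0.0561 without DKO 1, for Kcnh7 0.0730 without DKO 3, for Ppp2r2b 0.166 without DKO 1, for Slc16a14 0.0974 without DKO 1, for Ube2ql1 0.131 without DKO 1 and for Gadd45g 0.0974 without DKO 1.

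**Figure D2:**
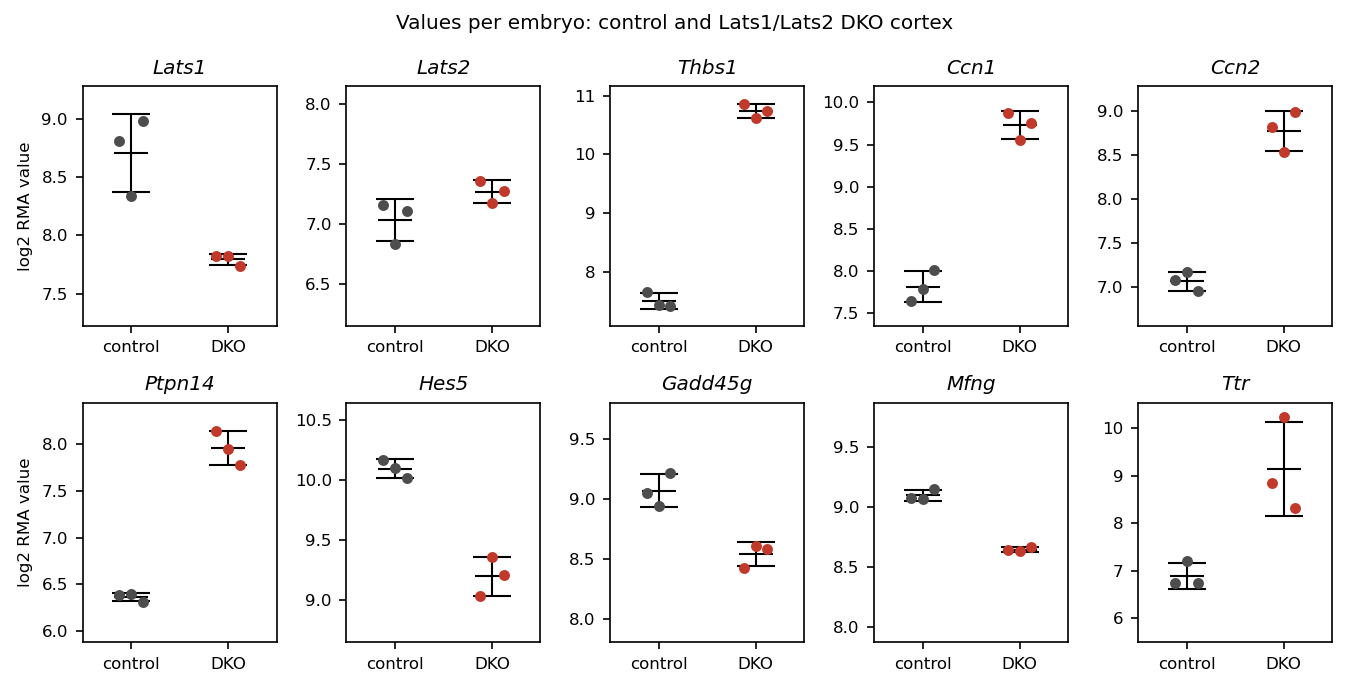
Log2 RMA values of 10 named genes, with 1 point per embryo (control grey, DKO red), a long horizontal mark for the group mean and error bars of 1 SD (n = 3), on axes that differ between panels. The groups do not overlap for any of the 10 genes, Lats1 is lower and Lats2 is not, and the DKO points of Ttr are spread from 8.33 to 10.25.

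Canonical targets of YAP and TAZ included several of the largest increases. Of 20 measured members, 8 rose, 0 fell and 12 did not pass the test over all genes, and 8 rose and 0 fell when adjusted over the list alone. The 4 members with the smallest p were Ptpn14, a phosphatase that binds YAP, at 1.59 ± 0.09 (SE), Ccn1 at 1.91 ± 0.11 (SE), F3, the coagulation initiator tissue factor, at 1.45 ± 0.09 (SE), and Ccn2 at 1.71 ± 0.11 (SE). Ccn1 and Ccn2 encode matricellular proteins, and their 3.77-fold and 3.28-fold increases exceeded the spread between embryos in each group. The list had a median log2 fold change of 0.16 and was shifted upwards by camera with an adjusted p of 3.74e-13, but the adjusted p was 0.296 with an estimated correlation. With fry it was 0.0372.

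Components of the Hippo pathway itself rose in part. Of 22 measured members, 6 rose, 0 fell and 16 did not pass, and 7 rose and 0 fell when adjusted over the list alone. The clearest were Ajuba, a LIM-domain protein that inhibits Lats kinases, at 1.54 ± 0.11 (SE), Wwc2 at 1.19 ± 0.08 (SE) and Wwc1 at 0.85 ± 0.08 (SE), which encode WW-domain scaffolds upstream of Lats, and Tead3, a DNA-binding partner of YAP and TAZ, at 0.61 ± 0.07 (SE). The coactivator genes themselves were chosen after their values were seen: Yap1 had a log2 fold change of 0.01 ± 0.07 (SE) and an adjusted p of 0.966, and Wwtr1, which encodes TAZ, 0.27 ± 0.06 (SE) and 0.0779. The median of the list was 0.01 and its mean 0.22, camera gave an upward shift with an adjusted p of 2.67e-04, and the adjusted p was 0.551 with an estimated correlation and 0.153 on ranks. The median turned to -0.03 without control 2 and to -0.0037 without DKO 1, while camera still called the list (adjusted p 0.00209 and 0.00590).

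Some genes of the actin cytoskeleton and focal adhesions rose. Of 19 measured members, 5 rose, 0 fell and 14 did not pass, and 10 rose and 0 fell when adjusted over the list alone. Besides Tpm1, these were Actn1, which encodes the actin crosslinker alpha-actinin, at 0.88 ± 0.07 (SE), Anxa2, an annexin, at 1.03 ± 0.13 (SE), Tln1, which encodes the integrin activator talin, at 0.55 ± 0.08 (SE), and Zyx, which encodes zyxin and was named after its values were seen, at 0.42 ± 0.08 (SE). Tln1 and Zyx lost their calls in 5 of the 6 fits that left out 1 array, with adjusted p up to 0.0728 without DKO 3 for Tln1 and 0.131 without DKO 1 for Zyx. The list had a median of 0.27 and an adjusted p of 2.92e-11 by camera, of 0.354 with an estimated correlation and of 0.0829 with fry.

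Intermediate progenitor and neurogenic genes had lower means in DKO. This held for all 15 measured members, of which 3 fell, 0 rose and 12 did not pass over all genes, while 15 fell when adjusted over the list alone. Mfng, a glycosyltransferase that modifies Notch receptors, fell by 0.45 ± 0.06 (SE) on the log2 scale, Gadd45g by 0.53 ± 0.09 (SE) and Hes6, a neurogenic antagonist of Hes1, by 0.33 ± 0.06 (SE). Rhbdl3 had a log2 fold change of -0.71 ± 0.15 (SE) with an adjusted p of 0.0634, and Eomes, the marker of intermediate progenitors and named after its value was seen, -0.44 ± 0.11 (SE) with an adjusted p of 0.103. The median of the list was -0.44, with an adjusted p of 3.34e-12 by camera, 0.296 with an estimated correlation and 0.0464 with fry. The call for Mfng held in each fit that left out 1 array, while that for Gadd45g was lost in 4 of the 6 (adjusted p up to 0.0974 without DKO 1) and that for Hes6 in all 6 (up to 0.135 without control 1). Markers of the cortical hem and choroid plexus had higher means in the same DKO arrays, with a median of 0.43 and a camera adjusted p of 9.81e-10, or 0.296 with an estimated correlation.

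Postmitotic neuron markers had mostly lower means in DKO, with no single call and a list adjusted p of 0.551 with an estimated correlation. Of 21 measured members, 0 rose and 0 fell over all genes, 16 had a lower mean in DKO, and 8 fell when adjusted over the list alone. Nhlh1 had a log2 fold change of -0.36 ± 0.08 (SE, adjusted p 0.0622) and Neurod6 of -0.54 ± 0.15 (SE, adjusted p 0.123). The median was -0.18 and the camera adjusted p 4.83e-04 with the preset correlation. Parting the arrays in other ways gave this list a lower unadjusted camera p than genotype did (3.44e-07 against 1.89e-04).

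Apical progenitor markers did not shift as a list. Of 19 measured members, 2 rose, 1 fell and 16 did not pass, and 5 rose and 5 fell when adjusted over the list alone. Hes5 fell as given above, Hmga2, a chromatin protein of early progenitors, rose by 0.51 ± 0.09 (SE), and Slc1a3, the glial glutamate transporter, rose by 0.40 ± 0.08 (SE). Vim had a log2 fold change of 0.32 ± 0.07 (SE) with an adjusted p of 0.0573. The calls for Hmga2 and Slc1a3 were lost in 4 and in 6 of the 6 fits that left out 1 array, with adjusted p up to 0.147 without control 1 for Hmga2 and 0.147 without control 3 for Slc1a3. The list had a median of 0.03 and a camera adjusted p of 0.326.

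Markers of the cortical hem and choroid plexus, the dorsal midline tissue next to the cortex, had higher means in DKO. This held for all 14 measured members, of which 2 rose, 0 fell and 12 did not pass, and 9 rose when adjusted over the list alone. Lmx1a, a transcription factor of the hem and roof plate, rose by 0.47 ± 0.06 (SE), and Ttr rose as given above. Wnt5a had a log2 fold change of 0.38 ± 0.08 (SE, adjusted p 0.0680) and Rspo2 of 0.71 ± 0.18 (SE, adjusted p 0.10). The median was 0.43 and the camera adjusted p 9.81e-10, or 0.296 with an estimated correlation, and the fry adjusted p was 0.0829. Lmx1a lost its call without control 1 (adjusted p 0.0583), control 3 (0.0540) and DKO 1 (0.0508), and in each of these 3 fits 0 members of the list passed. Parting the arrays by embryo sex gave this list a lower unadjusted camera p (3.99e-14) than parting them by genotype (1.71e-10).

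Of 17 measured genes of the integrated stress and unfolded protein response, 3 rose and 0 fell, and 10 rose when adjusted over the list alone. These were Chac1, a glutathione-degrading enzyme, at 0.68 ± 0.10 (SE), Asns, asparagine synthetase, at 0.55 ± 0.09 (SE), and Atf3, a stress-induced transcription factor, at 0.77 ± 0.14 (SE). Their adjusted p reached 0.0741 for Chac1 and 0.0878 for Asns without control 3, and 0.145 for Atf3 without control 3. The median of that list was 0.23, with an adjusted p of 5.50e-08 by camera and 0.296 with an estimated correlation. Of 12 hypoxia and glycolysis genes, 1 rose and 0 fell, and 7 rose when adjusted over the list alone. Egln3, an oxygen-sensing prolyl hydroxylase, rose by 0.86 ± 0.11 (SE), and Vegfa had a log2 fold change of 0.50 ± 0.10 (SE, adjusted p 0.0572). The hypoxia list had a median of 0.21 and a camera adjusted p of 3.09e-06, or 0.354 with an estimated correlation, and 5 of its members rose when DKO 2 was left out. Of 23 measured p53 targets, 1 rose and 1 fell, and 4 rose and 2 fell when adjusted over the list alone. Ccng1, which encodes cyclin G1, rose by 0.74 ± 0.09 (SE) and Btg2, an antiproliferative gene, fell by 0.41 ± 0.08 (SE). The p53 list was not called by camera (adjusted p 0.0930), and its adjusted p was 0.0493 with no filter on dim genes. Cdkn1a, the cell cycle inhibitor p21 and named after its value was seen, had a log2 fold change of 0.55 ± 0.16 (SE, adjusted p 0.139). Of 15 immediate early genes, 1 rose and 1 fell, and 2 rose and 1 fell when adjusted over the list alone. They were Fosl2, an AP-1 subunit, at 0.73 ± 0.09 (SE), and Btg2, which both lists hold, and the camera adjusted p was 0.235. Btg2 lost its call in each fit that left out 1 array, with adjusted p up to 0.149 without control 1.

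Cell cycle and housekeeping lists held no call over all genes. None of 27 DNA replication genes, 21 mitosis genes, 20 DNA damage response genes or 26 genes of the RNA polymerase II machinery passed the limma test over all genes or when adjusted over the list alone, and their camera adjusted p values were 0.937, 0.399, 0.302 and 0.516. The RNA polymerase II list had a median of -0.0090 and a mean of -0.0070, while camera placed it above the other genes. Mki67, the proliferation antigen, had a log2 fold change of -0.12 ± 0.06 (SE, adjusted p 0.438), and Orc1, a subunit of the origin recognition complex, of 0.21 ± 0.07 (SE, adjusted p 0.200). Ribosome biogenesis genes had slightly higher means in DKO, with a list adjusted p of 0.530 with an estimated correlation. This held for all 20 measured members, and for 14 of 20 without DKO 1, while 0 passed over all genes and 1 rose when adjusted over the list alone. Heatr1, which encodes a factor for ribosomal RNA transcription, had a log2 fold change of 0.29 ± 0.06 (SE, adjusted p 0.0728), and Ncl, which encodes nucleolin, of 0.23 ± 0.07 (SE, adjusted p 0.176). The median of the list was 0.09 and its camera adjusted p 6.62e-06 with the preset correlation, and another split of the arrays gave a lower unadjusted camera p than genotype did (1.65e-06 against 2.01e-06).

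The 7 lists of endothelial, microglia, ventral telencephalon, meningeal, erythroid, surface epithelium and retina markers held no member past the test over all genes or when adjusted over the list alone. All 15 endothelial and pericyte markers had lower means in DKO, with a median of -0.19 and a camera adjusted p of 0.00105, or 0.577 with an estimated correlation. Cdh5, the endothelial cadherin, had a log2 fold change of -0.44 ± 0.14 (SE, adjusted p 0.194). Without DKO 2 the endothelial median was -0.05 and the camera adjusted p 0.124. Microglia and macrophage markers had a median of -0.15 over 13 genes and a camera adjusted p of 0.0450, or 0.664 with an estimated correlation, and the call was lost without DKO 2 (0.538), without control 2 (0.205) and with the Y-linked covariate (0.123), and also with the stricter filter on dim genes, array weights or a trended variance. All 11 ventral telencephalon markers had lower means in DKO, with a median of -0.21 and a camera adjusted p of 0.0153, or 0.558 with an estimated correlation. Dlx2, a homeobox gene of the ganglionic eminences, had a log2 fold change of -0.66 ± 0.19 (SE, adjusted p 0.137). The ventral call was lost without control 2 (0.372), DKO 1 (0.0527) and DKO 3 (0.163). The 6 arrays can be parted 3 against 3 in 10 ways, genotype included. For the endothelial list 6 of these gave an unadjusted camera p as low as genotype, for microglia 7 and for ventral markers 5. The lowest from another split were 1.154e-06, 4.395e-06 and 1.87e-11, against 4.548e-04, 0.0235 and 0.0073 by genotype. Meningeal (14 measured), erythroid (11), surface epithelium (10) and retina (9) markers were not called by camera, with adjusted p values of 0.235, 0.235, 0.746 and 0.249. The surface epithelium list had a median of 0.0029 and a mean of -0.0057, which differ in sign. Meningeal and erythroid markers were called lower without DKO 1 (adjusted p 5.75e-04 and 0.0274), and erythroid markers also without DKO 3 (0.0493). Without DKO 2 the medians of both lists turned positive, at 0.06 for meningeal and 0.08 for erythroid markers, with 9 of 14 and 7 of 11 members higher in DKO and adjusted p values of 0.432 and 0.259.

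**Figure D3:**
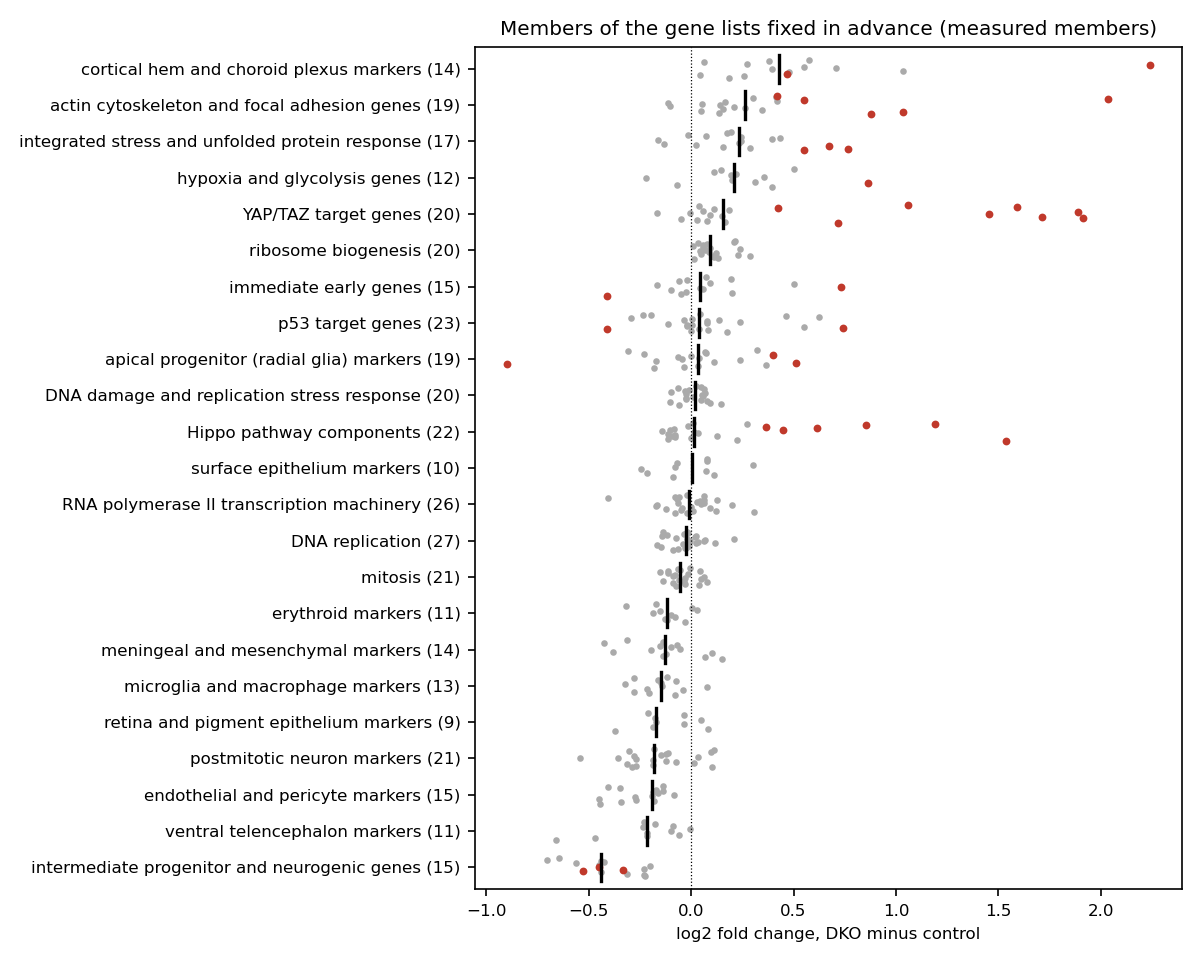
Log2 fold change (DKO minus control, horizontal axis) of each measured member of the 23 gene lists tested, with the number of measured members in parentheses, sorted by median. Red points passed the limma test over all genes at an adjusted p under 0.05, grey points did not, and black bars mark medians, which run from -0.44 for the neurogenic genes to 0.43 for the hem and choroid plexus markers.

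Over all 23 lists, 12 were shifted by camera with its preset correlation, 7 upwards and 5 downwards. None kept a call with an estimated correlation, and fry called 2, the YAP/TAZ targets and the neurogenic genes. The embryos also differed in sex. Xist stood near 11 on the log2 scale in control 1 (11.09), control 3 (11.02) and DKO 3 (10.90) and between 4.63 and 4.79 in control 2, DKO 1 and DKO 2, and the Y-linked genes Eif2s3y, Kdm5d and Uty divided the arrays in the opposite sense. With the level of the Y-linked genes as a covariate, an alternative added after seeing the data, 165 genes rose and 25 fell.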

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

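The tests on the position of the dissection and on dilution by other cells were chosen only after the result was seen. Rows of the array that carry no gene name here held a signal outside the comparison of named genes: of 9361 such rows tested with limma, 5 were higher in DKO than in control and 0 lower, and 656 had an unadjusted p under 0.05. One of the 5 (adjusted p 4.90e-04) stood at 9.12 ± 0.35 (SD, n = 3) in DKO cortex and at 4.83 ± 0.09 (SD, n = 3) in control, a level under the limit for dim genes (5.02) and not shown to be above background, so the size of its increase is uncertain. That row had a log2 fold change of 4.29, and the next ones rose by 3.52, 3.43 and 3.30. Their control means were 5.11, 4.59 and 6.18, of which 4.59 also lay under that limit. Each of these increases was larger than that of Thbs1 (3.24), the largest among the named genes. The smallest difference among the 5 was a log2 fold change of 1.04. Whether these rows measure separate transcripts or are control probes was not given in the sources used here. Calls were rarer than among the named genes, where 288 of 16724 were called and 2604 had an unadjusted limma p under 0.05. Of 1530 tested rows with several gene symbols, 0 passed the limma threshold and 141 had an unadjusted p under 0.05.

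The hem and choroid plexus markers were higher in DKO for 14 of 14 measured members. With the Y-linked covariate 14 of 14 members stayed higher in DKO. Their median was 0.35 in place of 0.43, with 1 call in place of 2. The camera adjusted p of 4.47e-09 in that fit used the preset correlation, with which other splits of the arrays also called lists. It therefore cannot decide on sex. Choroid tissue in DKO 2 alone is argued against by the fit without that array, in which 14 of 14 members stayed higher with a median of 0.39. The camera adjusted p was 2.29e-08 there and ranged from 4.02e-12 to 0.296 over all settings tried. A dissection boundary nearer the dorsal midline in DKO stays open, because 11 of 11 ventral telencephalon markers had lower means in DKO, but only 8 of 11 without control 2 or without DKO 3. In 5 of the 10 splits of the arrays, genotype included, the ventral list had an unadjusted camera p as low as by genotype. A split of the arrays by sex gave this list an unadjusted camera p of 3.99e-14, below the 1.71e-10 of the split by genotype, so the markers also varied between embryos of one genotype. A change in dorsal midline tissue caused by the loss of Lats1 and Lats2 is a hypothesis that would give the same pattern and was not tested.

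The neurogenic genes had lower means in DKO for 15 of 15 members. Dilution of the cortical cells by cells without the apical progenitor markers would lower those markers too. Their median was 0.03, with 5 higher and 5 lower in DKO when adjusted over the list alone, against a median of -0.44 for the neurogenic genes. The medians differed by 0.471 (permutation p = 2e-05 over genes, which are not independent replicates). Equal lowering of both lists is not what they show. Both medians were known when the test was chosen, so it cannot exclude such dilution. Cells that carry the apical markers would not lower them, so dilution by such cells stays open as well. With the Y-linked covariate 15 of 15 neurogenic genes stayed lower in DKO. Their median was -0.37 in place of -0.44, with 1 call in place of 3. The camera adjusted p of 5.46e-12 in that fit used the preset correlation and cannot decide on sex. Over all settings it ranged from 1.03e-13 to 0.296, the highest with an estimated correlation. DKO embryos at a younger stage, whether from timing or from slower development, stay open: late progenitor genes lay below early ones by a mean log2 difference of -0.284 (exact permutation p = 0.0420 over 10 late and 3 early genes), though 0 of these 13 genes were called. These genes are not independent replicates either, so this p cannot decide on stage. The late genes Tnc (0.24), Ptn (0.12) and Dbi (0.05) had higher means in DKO, and the other late genes had lower ones. Fewer progenitors entering neurogenesis after loss of Lats1 and Lats2 is a hypothesis that would give the same result and was not tested apart from stage.

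Lats1 was lower and Lats2 was not. Differences linked to the targeted loci, such as strain sequence carried along with the floxed alleles, would change neighbouring genes, and 1 of 40 tested neighbours was called, Samd5, which lies near but not beside Lats1, with a log2 fold change of 0.53 (one-sided Fisher's exact p = 0.501 against all other genes), a number that cannot decide. Samd5 itself lost its call without control 3 (adjusted p 0.0516) and without DKO 1 (0.0588). Whether the Lats2 probes lie inside the deleted part stays open, as does an increase of a truncated Lats2 transcript.

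The split by genotype called 288 genes, and the highest number in any other of the 10 splits of the 6 arrays was 12, so 1 split of 10 reached the real count. Those 12 came from the split by embryo sex, and 11 of them lie on chromosomes X or Y. For gene lists the real split called 12 and the highest other split 14, so that 3 of the 10 splits called 12 or more. With 10 splits the share cannot fall below 0.05 in either case. For 6 of the 23 lists the camera p was lowest in the real split, namely YAP/TAZ targets, Hippo components, neurogenic genes, actin and focal adhesion, hypoxia and glycolysis, and the stress responses.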

How the results depend on the processing

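All 288 changed genes kept their sign in every alternative in which they were tested, but most of this was fixed in advance. Their groups did not overlap, so leaving out 1 array could not turn a sign, and other variance estimates leave the fold change as it is. When all rows were tested, only the row of a gene with the highest mean was compared, and the rows of 1 changed gene differed in sign. The number of changed genes depended on how the variance was estimated. Medians of gene lists did turn: without DKO 2 the meningeal median went from -0.13 to 0.06, the erythroid one from -0.12 to 0.08 and that of DNA replication from -0.02 to 0.02, and without control 2 the Hippo median went from 0.01 to -0.03. Lists with medians near 0 (DNA damage response, RNA polymerase II machinery, apical progenitors, surface epithelium and immediate early genes) also changed sign in some fits. The count of changed genes moved from 288 to 485 with a trended variance (323 higher, 162 lower) and to 530 with a trended and robust one (345 higher, 185 lower), which put the share of increases at 66.6% and 65.1% in place of 79.2%. The stricter dim filter gave 134 decreases and a share of increases of 68.2%, and array weights gave 123 decreases; the cause was not tested for these 4 settings. A repeated quantile normalization gave 325 genes, each array's median set to 0 gave 320, and no dim filter 246. Unmoderated statistics called 0 genes (0 higher, 0 lower), with 2178 at an unadjusted p under 0.05 and an adjusted p of 0.233 for the log2 fold change of Lats1 (-0.91), since 4 degrees of freedom carry the test alone. A 1.5-fold minimum left 152 genes (140 and 12), and an adjusted p under 0.01 left 119 (111 and 8). Leaving out 1 array gave 134 to 314 changed genes, 121 to 260 higher and 11 to 54 lower, with fewer samples in each fit: 148 without control 1, 193 without control 2, 134 without control 3, 145 without DKO 1, 314 without DKO 2 and 144 without DKO 3. The log2 fold change of Lats1 ranged from -1.10 to -0.78 over these fits, and that of Lats2 from 0.14 to 0.30, never past the threshold. Adding the Y-linked covariate, chosen after seeing the data, gave 190 genes (25 lower), of which 181 were among the 288. Leaving out chromosomes X and Y, also added later, gave 293. With the replicate block, 200 genes were called (176 higher, 24 lower) and 181 were shared. Deviations of same-numbered arrays correlated at -0.066, 0.172 and 0.127, and not every array correlated best with its own number. With 3 arrays per group these correlations cannot show whether same-numbered samples shared a litter or a day. For gene lists, camera called 0 of 23 with an estimated correlation and fry 2, against 12, and 10 to 13 when 1 array was left out; the cause was not tested. Named genes kept direction and side of the threshold in 1841 comparisons with alternatives, lost the call in 145 and gained one in 44. The 1841 include genes without a call in the main fit, which had none to lose. Unmoderated statistics, which called 0 genes, took the call from 44 named genes and left 64 as they were. List p values kept their side in 421, lost it in 33 and gained it in 4. The 421 likewise include lists without a call in the main fit, where 12 of 23 were called. Camera has no robust setting, so that alternative was not run for lists. The array has no signal over background at hand here, so changes of dim genes stay uncertain.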

Other observations

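The genes and the tests of neighbouring genes in this part were chosen after the values were seen, and the genes describe biology outside the fixed lists. Irs2 rose by 1.43 and Irs1 by 0.83 on the log2 scale, both encoding docking proteins of the insulin receptor, and Eif4ebp1, a repressor of cap-dependent translation, rose by 1.21. Klf5, a zinc-finger transcription factor, rose by 0.96, Pdpn, the membrane glycoprotein podoplanin, by 1.16 and Lipg, endothelial lipase, by 1.64. Vgll3, which encodes a cofactor of TEAD proteins, rose by 1.45, though its adjusted p was 0.0528 without control 3 and 0.0563 without DKO 1. The collagen-modifying genes P4ha3 (1.27) and Tll2 (1.25) and the matrix gene Sparc (0.78) rose as well, as did Plod2 (0.65) and Tll1 (0.66), which each lost the call in 5 of the 6 fits that left out 1 array (adjusted p up to 0.126 for Plod2 and 0.0948 for Tll1, both without control 1). All of these except Vgll3, Plod2 and Tll1 stayed past the threshold without each array in turn, and all kept it with a repeated quantile normalization and with each array's median set to 0.

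Beside Hes5, the Notch targets Hey1 (-0.45) and Nrarp (-0.45) fell, the latter with an adjusted p of 0.0540 without control 3, whereas Hes1 had a log2 fold change of 0.37 and an adjusted p of 0.121. Among genes used as astrocyte markers in later life, Aldoc (-0.76), Ndrg2 (-0.93) and Kcnj10 (-0.44) fell, while Clu (1.33), Aldh1l1 (0.79) and Mlc1 (0.43) rose. Mmd2 (-0.53) fell and Slc1a3 (0.40) rose too, with the call lost in 5 of 6 fits for Mmd2 (adjusted p up to 0.0794) and in 6 of 6 for Slc1a3 (up to 0.147). Of the first 6, Aldoc and Clu kept the call without each array in turn, and the adjusted p of the others reached 0.0561 for Ndrg2, 0.0902 for Kcnj10, 0.123 for Aldh1l1 and 0.0972 for Mlc1.

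Changed genes lay next to each other more often than when called genes were placed at random and singly. In the RefSeq gene order of GRCm38.p6, 18 neighbouring pairs of tested genes were both called, against a median of 5 when the 286 called genes in that order were placed at random (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The direction was the same in 17 of the 18 pairs, against a median of 12 when directions were dealt at random among the called genes (one-sided permutation p = 0.00666, 100000 resamples). Both tests treat genes as independent. Pairs that share a gene, such as Mt3 with Mt2 and Mt2 with Mt1, were each counted, and related genes or shared probe signal were not set apart. These p values therefore cannot show that position itself matters. The pairs included the metallothionein genes Mt1 (0.73), Mt2 (1.07) and Mt3 (0.95), and the pairs Steap1 (2.32) with Steap2 (1.03) and Cldn12 (1.75) with Gtpbp10 (0.43). The call was lost for Mt1 without control 1, control 2, control 3 or DKO 1 (adjusted p up to 0.0974) and for Gtpbp10 without control 1 (0.0551).

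Over all rows, the array most correlated with a given array had the same genotype for 4 of 6 arrays, with control 2 closest to DKO 2 and DKO 3 closest to control 1. Over the 16180 tested genes off chromosomes X and Y, 6 of 6 arrays were closest to an array of their own genotype. This comparison also left out dim genes and rows without exactly 1 gene symbol. The change cannot be credited to chromosomes X and Y alone. All 4 measured sex-linked genes divided the arrays in the same way, with control 1, control 3 and DKO 3 on the same side and a gap of 6.11 on the log2 scale for Xist. Over all rows, arrays on the same side correlated at 0.9905 or more, and arrays on different sides at 0.9854 or less. Whether this division came from sex alone was not tested.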
